A study of Mus musculus with 24 samples.

How the data were processed

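RNA sequencing libraries from the epididymal fat of male C57BL/6J mice were analysed, 24 in all, 3 for each of 8 groups. Per the labels the mice ate a high-fat diet, for Warm and Cold from 6 weeks of age, until they weighed 38-42 g. M1 and M2 adipose tissue macrophages and adipose progenitors were sorted from mice kept at thermoneutrality (Warm) and from mice harvested on day 14 of a cold exposure, 7 days at 18 °C and then 7 days at 4 °C (Cold). M1 and M2 macrophages were also sorted from thermoneutral mice 8 days after an intraperitoneal dose of the antibody bFKB1 (10 mg/kg), an activator of the receptor complex that FGF21 uses. For Warm and Cold, sorted cells of 5 mice were pooled per library; pooling is not stated for bFKB1. Poly-A RNA was selected for the Warm and Cold libraries. No vehicle-treated group is among the labels, and Warm served as the control of bFKB1.

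The deposited values are raw counts per gene, with 1 column per library in 2 tables, 1 holding the Warm and Cold libraries and 1 the bFKB1 libraries. The tables were made by the authors; per the submitters' processing notes GSNAP, CASAVA 1.8 and the genome build GRCm38 were used for both tables and SAMtools for the table of Warm and Cold, while the program that counted reads and the gene annotation are not given in the sources used here. Columns were matched to samples through the sample descriptions. For the bFKB1 libraries the numbers in titles and in sample characteristics differ; the title numbers are used to name libraries. Rows that carry a date in place of a gene symbol, 27 with 0.148% to 0.192% of the counts of a library, were left out, and the same 21063 gene rows in both tables were used. Among their symbols, 20079 occur in GENCODE M21 on GRCm38, 839 were matched through a synonym and 145 had no match. Libraries held 14.4 to 34.6 M counts (Warm M1 20.6 to 23.4, Cold M1 22 to 24.2, bFKB1 M1 21.1 to 24.8, Warm M2 17.7 to 20.5, Cold M2 14.4 to 23.4, bFKB1 M2 21.3 to 23.4, Warm progenitors 29.1 to 34.6, Cold progenitors 26.4 to 33.6), and the 10 most abundant genes took 7.88% to 21.08%.

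Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the groups, TMM scaling, 1 mean per population and condition, quasi-likelihood fit and F-test, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Cold against Warm in macrophages, M1 against M2 in the warm and the difference of the cold effects (M2 minus M1) came from 1 fit of 12 libraries. The bFKB1 contrasts with Warm came from a fit of the 12 Warm and bFKB1 macrophage libraries, bFKB1 against Cold from a fit of all 18 macrophage libraries, and the progenitors from a fit of 6. Levels are CPM, counts over the library total. For each comparison it was counted, on CPM, for how many genes all libraries of 1 group lay above all of the other. Genes move together, so an excess over the 10% expected by chance is a description and no test. These contrasts, the lists, the rule for naming genes and the alternatives of the last paragraph were fixed before the data were examined.

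A total of 35 gene lists was tested where at least 5 members passed the filter: macrophage core, lipid-associated macrophage, resident macrophage, alternative activation, pro-inflammatory, interferon response, MHC class II, monocyte, dendritic cell, cell cycle, lysosome, sterol synthesis, LXR and efflux, fatty acid oxidation, respiratory chain, glycolysis and hypoxia, catecholamine handling, unfolded protein response, immediate early, antioxidant and iron, FGF and MAPK feedback, progenitor, matrix, adipogenic regulators, lipogenesis, mature adipocyte, thermogenic adipocyte, stromal inflammation, smooth muscle, T and NK cell, B cell, granulocyte and mast cell, endothelial, mesothelial and epididymal epithelium. For each list members called higher and lower were counted, with p adjusted over all genes and also over the list alone. Camera (limma 3.58.1) with a preset gene correlation of 0.01 tested each list, and camera with an estimated correlation and fry were run beside it. With the preset value many lists were also called after libraries had been regrouped against their labels, so its small p-values are weak support.

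Named genes followed a rule. For the comparisons of treatments with Warm and of M1 with M2 it took genes past the threshold with an absolute log2 fold change of at least 1, a mean of at least 5 CPM in 1 group and no overlap of libraries, predicted genes left out, the 10 that rose most and the 10 that fell most. To these came up to 4 called members with the smallest p of each list, and Itgax, Mrc1, Emr1, Cd68, Pdgfra, Ly6a, Fgfr1 and Klb in any case. Comparisons of effects gave 5 genes each way. A second choice by the same rule among genes with little progenitor RNA was added after the data were seen, and Clec9a for bFKB1 against Cold in M1 and Retnla for bFKB1 in M2 come from it alone. The texts give part of the genes that qualify, and some are not reported here.

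RNA of another sorted population was estimated per library. For progenitor RNA in macrophage libraries 46 genes served (at least 100 CPM in progenitors and at most 1% of that in the lowest macrophage library), and the share is the median of their level over that in progenitors of the same condition, with Warm progenitors for bFKB1. For macrophage RNA in progenitor libraries the 16 macrophage core genes served, set against the mean of M1 and M2. In mixtures of Cold M2 and Cold progenitor counts at 5%, 15% and 30%, the shares came back as 6.5%, 16.4% and 31.1%. Then 2 refits were run, both added after the data were seen: genes that owed under 10% of their counts to the other population in every library compared, with TMM scaling of their own, and all genes after the expected counts had been taken off. The filter of the first is not independent of the changes tested, since a fall in a gene's counts raises the share it owes.

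The replicate numbers were checked as pairs: after removal of group means, libraries of the same number had correlated residuals in all 3 pairs for Warm and Cold progenitors (0.14 to 0.23), Warm M1 and Warm M2 (0.21 to 0.32), bFKB1 M1 and bFKB1 M2 (0.16 to 0.52) and Cold M1 and bFKB1 M1 (0.25 to 0.7). The labels do not state that numbers pair the libraries, so the numbers entered as a block only in an alternative. With the block 5349 genes were called for cold in M1, 999 in M2 and 4735 in progenitors, 2445 and 875 for bFKB1 in M1 and M2, and 5189 for M1 against M2. For the difference of the cold effects it called 334, of which 190 were among the 300 called without it. For that of the bFKB1 effects it called 0, and for bFKB1 against Cold 3258 in M1 and 403 in M2.

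Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, fits of the 2 compared groups alone, the replicate block, and each library left out in turn. The whole procedure was tested on simulated data in which 200 genes had been changed 1.5-, 2- or 4-fold. Genes were drawn independently, no uneven progenitor RNA was put in, and most real contrasts called far more genes. The rates below belong to that setting and may differ in the real data. Calls recovered 50.7%, 71.6% and 89.4% of them for cold in M1, 44.8%, 62.7% and 86.4% in M2, and 14.9%, 61.2% and 90.9% in progenitors, where 10.5% of the calls were false. The figures were 59.7%, 77.6% and 93.9% for bFKB1 in M1, 47.8%, 71.6% and 86.4% in M2, 56.7%, 65.7% and 87.9% for M1 against M2, 16.4%, 56.7% and 81.8% for the difference of the cold effects and 28.4%, 58.2% and 80.3% for that of the bFKB1 effects. For bFKB1 against Cold they were 50.7%, 79.1% and 89.4% in M1 and 52.2%, 71.6% and 89.4% in M2.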

Results

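Macrophages of the M1 and M2 populations and adipose progenitors from the epididymal fat of obese male mice were compared between thermoneutral (Warm) and cold-exposed animals, and the macrophages also between Warm animals and animals given the antibody bFKB1. The first contrast below describes the 2 macrophage populations themselves, the others the 2 treatments. Changes are log2 fold changes, levels are the mean CPM of 3 libraries, and a gene is said to have risen or fallen where its adjusted p was under 0.05.

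In Warm mice the M1 and M2 populations carried different transcripts for much of what macrophages do. M2 cells held more RNA of resident, scavenging macrophages, of interferon-stimulated genes and of immediate early genes. M1 cells held more RNA of lipid-handling macrophages, monocytes, antigen presentation, sterol synthesis, glycolysis and the respiratory chain. Itgax, which encodes the integrin CD11c, was higher in M1 by 2.80 (779 against 105 CPM), and Mrc1, the mannose receptor CD206, differed by -1.85 (1700 against 5760 CPM). For these edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p = 1.39e-06 and 6.84e-07. Both are sort markers of such macrophages and the gates are not in the labels, so these 2 differences may be built in by the sort. All 20 resident macrophage genes were lower in M1, with a median of -3.85: the lectins Cd209f and Cd209g (-7.43 for both), the hyaluronan receptor Lyve1 (-6.68), the chemokine Ccl8 (-6.44) and the ficolin Fcna (-5.87). Of 18 lipid-associated macrophage genes, 14 were higher and 1 lower, among them the elastase Mmp12 (2.68), Gpnmb (2.38) and cathepsin K (Ctsk, 2.07). Of 14 monocyte genes 11 were higher (12 when adjusted over the list alone), such as coagulation factor F10 (2.92) and fibronectin (Fn1, 2.13). MHC class II genes went 12 higher and 2 lower of 14, with H2-DMb2 at 2.91 and H2-DMb1 at 1.24. Among 12 dendritic cell genes 7 were higher and 2 lower, with the growth factor receptor Flt3 at 3.44 and Siglech at -4.78.

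The metabolic groups also parted the 2 populations in the warm. Sterol synthesis was higher in M1 for 17 of 24 genes (18 over the list alone). Glycolysis and hypoxia genes went 13 higher and 1 lower of 22, with the glucose transporter Slc2a1 at 1.81 and Vegfa at 2.19, and 18 of 25 nuclear-encoded respiratory chain genes were higher by small amounts, such as Uqcrfs1 (0.67) and Sdhb (0.39). Interferon-stimulated genes were lower in M1 for 18 of 30 and higher for 3 (Oas2 -2.32, Bst2 -0.87), and immediate early genes were lower for 13 of 16 (Ier3 -2.16, Fos -0.75). Catecholamine handling was lower for 4 of 7 genes: monoamine oxidase A (Maoa) differed by -3.16 (10.3 against 86.3 CPM). The iron exporter Slc40a1 (-4.58), heme oxygenase Hmox1 (-1.90) and the transferrin receptor Tfrc (-2.70) were lower, although the antioxidant and iron list as a whole went 3 higher and 6 lower of 16. The macrophage core list was lower for 10 of 16 genes and higher for 2 (C1qa -1.87, Mertk -1.38, Cd68 -0.47 and Emr1, the F4/80 gene now named Adgre1, -0.53). Camera with a preset gene correlation called the lists named in these sentences, from adjusted p = 5.71e-59 for the resident genes to adjusted p = 0.0404 for antioxidant and iron, 13 of 34 in all. With an estimated correlation the resident list held (adjusted p = 0.019) and the others did not (from adjusted p = 0.0819 for monocytes to 0.798 for the respiratory chain).

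Markers of other cell types were present in these libraries too. Endothelial markers were higher in M1 for 9 of 12 genes (Pecam1 1.55, 48.7 with SD 34.4 against 15.4 CPM) and T and NK cell markers for 6 of 10, with 1 lower (Il7r 2.15, Cd4 -3.37). Progenitor markers stood low in both populations: Pdgfra at 23 and 15 CPM (0.51, adjusted p = 0.518 by edgeR's quasi-likelihood test) and Ly6a at 20.8 and 10.8 CPM (0.83, adjusted p = 0.258). Fgfr1, the receptor that bFKB1 activates together with beta-klotho, was lower in M1 (-0.69; 483 against 735 CPM), while the beta-klotho gene Klb stood at 0.154 and 0.186 CPM, under the count filter. In total 5873 of 12981 genes differed, 2917 higher and 2956 lower in M1. The 3 libraries of each population did not overlap for 59.6% of genes, where chance gives 10%, and leaving out any 1 library gave 5038 to 5776 genes. All 36 called genes named for this contrast kept their call without any 1 library. Of these, 31 had not been picked for an absence of overlap, and 31 of the 31 had none. Such genes were called in the same libraries, mostly picked by small p, so here and below their lack of overlap is no separate support.

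Cold moved the M1 libraries in more than 1 way: macrophage genes changed, transcripts of adipose progenitors rose beside them, and several dendritic cell genes rose. Within the macrophage genes, lipid handling and lysosomal genes rose, while most pro-inflammatory and antigen presentation genes and several genes of alternative activation fell. Progenitor and matrix genes rose many-fold, and they rose unevenly from library to library. Of 19 progenitor genes 15 rose and 1 fell (16 and 1 over the list alone), with a median of 2.31, and of 30 matrix genes 25 rose and 2 fell, with a median of 2.18. Decorin (Dcn) went from 305 to 2500 CPM (3.06; SD 246 and 1520), Pdgfra from 23 to 232 CPM (3.35; SD 20.2 and 163), Ly6a from 20.8 to 113 CPM (2.47) and the gelatinase Mmp2 from 56.5 to 792 CPM (3.84). Scaled to 46 progenitor markers, progenitor RNA came to 28.4%, 12.63% and 8.77% of the 3 Cold M1 libraries, against 1.26%, 4.87% and 1.24% of the Warm M1 libraries and 0.83% to 1.86% of the M2 libraries. The largest rises among genes at 5 CPM or more included the fetuins Ahsg (5.59) and Fetub (4.51), Fgf10 (5.26), the stromelysin Mmp11 (4.92) and follistatin (Fst, 4.28), all left out of the restricted fit described next. Stromal inflammation genes rose for 13 of 20 and fell for 4, led by complement C3 (3.03, to 5060 CPM).

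**Figure D1:**
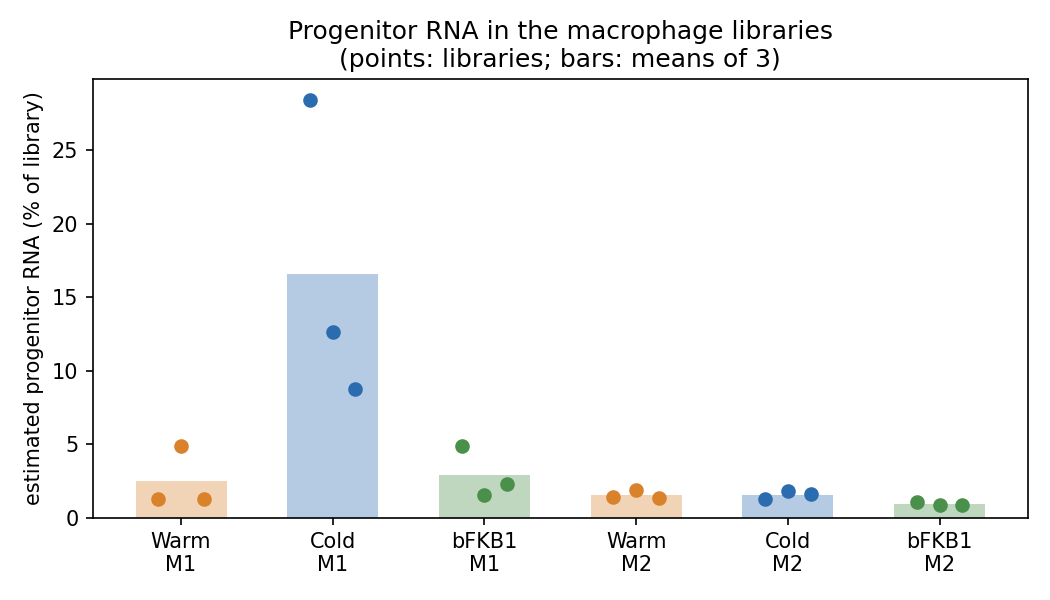
Estimated share of progenitor RNA (percent of the library, linear axis from 0) in each of the 18 macrophage libraries, points for libraries and bars for group means, by population and condition. The 3 Cold M1 libraries hold 28.4%, 12.63% and 8.77%, all above the other 15 libraries.

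Genes that owed under 10% of their counts to progenitors in every library were therefore fitted on their own, a step added after the data were seen. This fit called 981 of 2127 genes, 533 higher and 448 lower, where all genes in the fit had given the genes of this kind 296 higher and 790 lower, with changes lower by a median of 0.26. The filter depends on direction: a fall in Cold M1 raises the share a gene owes to progenitors, so falling genes were left out more readily. The list counts of this fit are therefore partly set by the filter. Lipid-associated macrophage genes rose in both fits, 14 of 18 with all genes (median 0.79) and 13 of the 14 left in the restricted fit (0.97). They included the fatty acid transporter Cd36 (0.87 with all genes and 1.13 in the restricted fit) and the lipid droplet coat Plin2 (0.62 and 0.88), and Ctsk (1.86) rose with all genes. Lysosomal genes rose for 17 of 28 (18 over the list alone) and for all 14 of the restricted fit, as cathepsin D (Ctsd, 0.85 and 1.12) and the proton pump subunit Atp6v1a (0.57 and 0.83) did. Pro-inflammatory genes fell for 18 of 24, with 1 higher, and for 10 of 16, with 1 higher, in the restricted fit: the chemokine Cxcl2 by -0.91 and -0.65, and Ccl2 by -1.38 with all genes. MHC class II genes fell for 11 of 14, and for 10 of 13 with 2 higher in the restricted fit (Ciita, their transactivator, -1.10 and -0.83; the costimulator Cd86 -0.95 and -0.68). Alternative activation genes fell for 6 of 16, and for 4 of 12 with 1 higher (Retnla -2.00 and -1.75, from 4170 to 1060 CPM; Batf3 -1.47 and -1.20). The lectin Mgl2 fell from 537 to 110 CPM (-2.32 and -2.09) and clotting factor F13a1 from 547 to 134 CPM (-2.05 and -1.80), within a resident list that went 6 higher and 8 lower of 20.

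Some directions in M1 turned on this scaling. The macrophage core list went 2 higher and 7 lower of 16 with all genes and 6 higher and 2 lower in the restricted fit: Cd68 rose by 0.29 and 0.55, and Emr1 did not change with all genes (0.05) and rose by 0.32 in the restricted fit. Cell cycle genes fell for 18 of 33 (21 over the list alone; Aurkb -0.73 and -0.46), but for only 5 of 28 in the restricted fit. Itgax changed by 0.18 (adjusted p = 0.471, edgeR's quasi-likelihood test) and by 0.44 in the restricted fit (adjusted p = 0.044), while Mrc1 fell in both (-0.81 and -0.55). Interferon-stimulated genes went 4 higher and 11 lower of 30 (Isg15 -1.13, and Oasl1 -0.83 and -0.55), and 3 of the 6 left in the restricted fit fell. Dendritic cell genes went 6 higher and 2 lower of 12, and 6 higher and 2 lower of 10 in the restricted fit. There Xcr1 rose by 2.79, Itgae by 2.69 and Clec9a by 1.94. Camera with the preset correlation did not call that list (adjusted p = 0.427). A changed share of dendritic cells was not told apart from changes within macrophages.

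Groups that progenitors also express could not be kept apart in this way, and their values stand beside that share of foreign RNA. Sterol synthesis fell for 13 of 24 genes, and unfolded protein response genes went 3 higher and 13 lower of 17 (Pdia4 -0.74, Asns 1.38). Fatty acid oxidation rose for 12 of 19 (Pdk4 2.06), and antioxidant and iron genes rose for 10 of 16 (Slc40a1 3.13, from 2.12 to 18.9 CPM; Nqo1 3.14; Prdx1 0.88). Immediate early genes went 2 higher and 9 lower of 16 (Dusp1 -0.73), and LXR and efflux genes 5 higher and 3 lower of 13 (Abca1 0.98). Mast cell transcripts rose from near zero, Cpa3 to 5.37 CPM (3.58) and Cma1 to 3.31 CPM (3.16), 6 of 9 granulocyte and mast cell genes rising and 2 falling. With the counts expected from progenitors subtracted, these genes kept their direction: Pdk4 2.15, Slc40a1 3.25, Pdia4 -0.83, Abca1 1.13, Cpa3 3.84 and Ccl2 -1.48. The subtraction gave extreme values for some genes of the progenitor, matrix and adipogenic lists (Gsn -16.01, Mmp3 13.29, Cebpd -11.26). It also left Pdgfra called (2.74, edgeR's adjusted p = 0.0239), so it did not remove progenitor RNA evenly.

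By edgeR's quasi-likelihood test 5705 of 12981 genes differed between Cold and Warm M1, 2910 higher and 2795 lower. Adjusted p was 0.000456 for Mgl2, 0.000275 for Retnla, 0.000313 for Cd36, 0.00025 for Ctsd and 0.00197 for Pdgfra. Camera called 16 of 34 lists in M1, from adjusted p = 2.87e-08 for pro-inflammatory genes to 0.0324 for stromal inflammation, and none with an estimated correlation, where the lowest adjusted p was 0.381. Fgfr1, left out of the restricted fit, fell (-0.44, and -0.74 with expected progenitor counts taken off, edgeR's adjusted p = 0.00135). Klb stood at 0.102 CPM. The 2 groups did not overlap for 51.7% of genes (chance, 10%), and 4064 to 6038 genes were called with any 1 library left out. Every Cold M1 library held more progenitor RNA than any Warm M1 library, which by itself can part the groups on CPM. Of 40 called genes named for cold in M1, 32 had not been picked for an absence of overlap, 31 of these had none (Cd68 overlapped), and 38 of all kept the call whichever library was left out; Cd68 lost it without Warm M1 1 or Cold M1 3, and Fgfr1 without any of Warm M1 1, Warm M1 3, Cold M1 2 and Cold M1 3.

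In M2 libraries, where progenitor RNA was put at 1.86% or less, cold lowered genes of monocytes and antigen presentation and raised genes for burning fat and the iron exporter Slc40a1. Interferon-stimulated genes rose. Some identity markers were not called with all counts: Mrc1 changed by 0.06 (adjusted p = 0.796, edgeR's quasi-likelihood test), Emr1 by -0.07 (adjusted p = 0.681) and Cd68 by 0.25 (adjusted p = 0.083), but with expected progenitor counts taken off Cd68 was (0.26, edgeR's adjusted p = 0.0183). MHC class II genes fell for 8 of 14 (9 over the list alone), with a median of -1.37, including the beta chain genes H2-Eb1 (-1.58, from 4930 to 1730 CPM) and H2-Ab1 (-1.54) and their transactivator Ciita (-1.36). Monocyte genes fell for 5 of 14 (6 over the list alone): the chemokine receptor Ccr2 (-2.77, from 231 to 35.2 CPM), Fn1 (-2.11, from 2460 to 595 CPM) and F10 (-2.10). Alternative activation genes fell for 4 of 16, the ribonuclease Rnase2a most (-3.16, from 183 to 21.6 CPM), then Retnla (-1.47), Il4ra (-0.86) and Batf3 (-0.84). Pro-inflammatory genes went 1 higher and 8 lower of 24 (12 lower over the list alone; Il6 -1.28, Cd44 -0.83), and Itgax fell from 105 to 40.1 CPM (-1.46). Among dendritic cell genes Flt3 fell (-2.55) and 3 of 12 were lower in all, with 1 higher.

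Fatty acid oxidation rose for 8 of 19 genes in M2 (12 over the list alone): Pdk4, which spares glucose, by 1.95 (from 19.8 to 79.9 CPM), Cpt1a by 0.44 and Acadl by 0.44. Slc40a1 rose by 2.52, from 48.1 (SD 9.07) to 289 CPM (SD 37.2); it lies on chromosome 1 at 45908068 to 45926523. Antioxidant and iron genes rose for 6 of 16 (9 over the list alone, with 1 lower), Gclm (0.90), Prdx1 (0.61) and ferritin Fth1 (0.44) among them. Interferon-stimulated genes rose for 7 of 30 (15 over the list alone), such as Ifit2 (0.94), Ifit3 (0.83) and Rsad2 (0.68). Lysosomal genes rose for 5 of 28 (Ctsd 0.80, Lipa 0.52) and lipid-associated genes for 5 of 18, with Itgax lower (Cd36 0.89, Ctsk 0.97). Unfolded protein response genes fell for 11 of 17, with 1 higher (Creld2 -1.05, Manf -0.92). The scavenger receptor Marco (2.32, from 3.81 to 19.9 CPM), the gelatinase Mmp9 (1.99) and the ficolin Fcna (1.74, from 768 to 2680 CPM) rose, and Mucl1 (-4.91, from 9.13 to 0.336 CPM) and Ear2 (-3.51) fell most. Mast cell markers rose from near zero (Cpa3 4.10, to 3.85 CPM; Cma1 3.97, to 3.22 CPM; 5 of 9 in the list), and so did adipocyte transcripts at low level (Cfd 1.79, from 2.36 to 8.59 CPM; Adipoq 1.10, from 3.49 to 7.88 CPM; 3 of 12 higher and 1 lower, or 7 and 1 over the list alone).

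In M2, 1312 of 12981 genes differed by edgeR's quasi-likelihood test, 573 higher and 739 lower. Adjusted p was 0.000282 for Slc40a1, Pdk4 and Fn1, 2.54e-05 for Rnase2a, 0.000457 for Ccr2, 0.00063 for H2-Ab1 and 0.00163 for Rsad2 and Itgax. Camera called 15 of 34 lists; 6 held with an estimated correlation, monocytes (adjusted p = 0.0257) and, each at adjusted p = 0.039, MHC class II, alternative activation, interferon response, fatty acid oxidation and granulocyte and mast cell. The lists lost were, among those above, pro-inflammatory (adjusted p = 0.187 with an estimated correlation), unfolded protein response (0.0903), antioxidant and iron (0.182), lysosome and lipid-associated macrophage (0.594), dendritic cell (0.143) and mature adipocyte (0.187). The 2 groups did not overlap for 40% of genes against 10% by chance. The count moved with the libraries: 531 genes without Warm M2 2, 580 without Cold M2 2, 721 without Cold M2 3, 813 without Cold M2 1 and 820 without Warm M2 1. Of 39 called genes named for cold in M2 34 were called in every such refit, and of 29 not picked for it 29 had no overlap: Lipa lost its call without Warm M2 1 or 2, Fth1 and Prdx1 without Warm M2 2, Adipoq without Warm M2 2 or Cold M2 2, and Ifit3 without Warm M2 3 or Cold M2 2.

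The cold effect itself differed between the 2 macrophage populations for a limited number of genes. The cold effect on interferon-stimulated genes was higher in M2 than in M1, and that on dendritic cell genes lower. Of 30 interferon genes 8 had a larger cold effect in M2 (15 over the list alone) and 0 a smaller one, with a median difference of 0.43: Oasl1 1.04, Isg15 1.01, Usp18 0.90 and Rsad2 0.74. With the counts expected from progenitors taken off, Rsad2 (0.54, edgeR's adjusted p = 0.1) and Mmp3 lost their call and the other genes named here kept theirs. For Mmp3 that fit gave -6.57 with a standard error of 26321.43, so it cannot tell whether the change remains. On genes with little progenitor RNA alone Rsad2 lost its call too (0.50, edgeR's adjusted p = 0.134). F13a1 (2.12), Padi4 (1.82), Bank1 (1.63), Ccl2 (1.34) and Mrc1 (0.87) also fell in M1 relative to M2. Flt3 (-2.94), the dendritic cell receptors Clec9a (-3.44) and Xcr1 (-5.38), Itgax (-1.64), Fn1 (-1.47) and F10 (-1.66) went the other way. So did genes that progenitors express, Adam12 (-4.18) and Mmp3 (-3.90), and 7 of 30 matrix genes were lower (29 over the list alone), beside progenitor RNA of 8.77% to 28.4% in Cold M1. By edgeR's quasi-likelihood test 300 of 12981 genes differed in their cold effect, 144 higher and 156 lower in M2 (3295 at an unadjusted p under 0.05); adjusted p was 0.00485 for Oasl1, 0.00768 for Isg15 and F13a1, 0.0106 for Flt3 and 0.0284 for Itgax. Camera called 17 of 34 lists, and the interferon list held with an estimated correlation (adjusted p = 6.98e-12 preset, 0.0286 estimated) while dendritic cell and matrix genes did not (adjusted p = 0.0886 and 0.305). DESeq2 called 1470 genes (491 higher and 979 lower in M2) and limma-voom 175 (102 and 73). The balance of higher and lower turned on the fit. On genes with little progenitor RNA alone 86 were higher and 171 lower, where all genes in the fit had given such genes 63 and 25. The differences themselves lay lower there, with F13a1 at 1.91, Mrc1 at 0.66, Flt3 at -3.18 and Itgax at -1.87. With expected progenitor counts taken off 694 were called, 298 higher and 396 lower. The count depended on single libraries: without 1 of the Warm M1 libraries it was 27, 1982 or 28, without Cold M1 2 or 3 it was 99 or 1188, without 1 of the Warm M2 libraries 41, 26 or 29, and without 1 of the Cold M2 libraries 146, 23 or 32. Only 6 of the 17 genes named here kept their call without each library in turn: Oasl1, Isg15, F13a1, Bank1, Ccl2 and Flt3. Of the other 11, all lost it without Warm M1 1, Warm M2 1, Cold M2 2 or Cold M2 3, 10 without Warm M1 3, Warm M2 2 or Warm M2 3, 5 without Cold M2 1 and 3 without Cold M1 2.

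Adipose progenitors answered cold with less RNA of matrix genes and with more of genes for lipid synthesis and adipogenesis. Interferon-stimulated genes rose, and respiratory chain genes fell slightly. Of 30 matrix genes 17 fell and 2 rose, with a median of -0.54: the inhibitor Timp1 (-2.18, from 713 to 166 CPM), the stromelysin Mmp3 (-1.47) and collagen Col6a2 (-0.80, from 7150 to 4330 CPM); Tgfbi rose (1.62). Tenascin C (Tnc, -2.54) and thrombospondin 4 (Thbs4, -2.57) fell as well. Lipogenesis genes went 10 higher and 2 lower of 17 (the sugar-sensing factor Mlxipl 2.26, Scd2 1.17, Lpin1 0.92, Dgat1 -0.98) and adipogenic regulators 9 higher and 2 lower of 21 (Rxra 0.86, Ebf1 0.65). Ppargc1a, a coactivator of mitochondrial genes, rose from 1.76 to 10.6 CPM (2.50) and Igfbp3 from 5.92 to 48.4 CPM (2.94), yet respiratory chain genes fell for 14 of 25 (16 over the list alone), each by little (Cox7a2 -0.69, Ndufs8 -0.54).

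Identity markers of progenitors moved both ways under cold, 3 of 19 higher and 3 lower: Pdgfra (0.88, from 574 to 1120 CPM) and Ebf2 (1.19) rose, lumican (Lum, -0.95) and Col15a1 (-0.96) fell, and Ly6a did not change (-0.17, adjusted p = 0.244 by edgeR's quasi-likelihood test). Feedback genes of FGF and MAPK signalling went 2 higher and 6 lower of 15 (3 and 6 over the list alone), Etv4 (-1.70), Spry1 (-0.81) and Dusp6 (-0.77) falling, while Fgfr1 rose by 0.31 and Klb stood at 0.0527 CPM. Interferon-stimulated genes went 13 higher and 1 lower of 30 (14 and 2 over the list alone), such as Gbp5 (1.43), Ifit2 (1.19) and Stat2 (0.63). The noradrenaline transporter Slc6a2 rose from 2.11 to 4.40 CPM (0.97). Contractile genes split, Tagln (-1.64) and Acta2 (-0.91) falling and Myh11 (0.71) and Abcc9 (1.31) rising.

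Macrophage RNA in the progenitor libraries was put at 2.59%, 2.06% and 0.36% in Warm and 0.18%, 1.01% and 0.25% in Cold, overlapping estimates that were not tested. Some genes abundant in macrophages were lower in Cold: MHC class II genes for 7 of 10 (Cd74 -2.52, H2-Aa -2.48), lipid-associated genes for 6 of 18, and macrophage core genes for 3 of 16, with 1 higher (Cd68 -1.87, adjusted p = 0.0742; Emr1 -1.65, adjusted p = 0.117; Itgax -1.80, adjusted p = 0.0919; Mrc1 -1.20, adjusted p = 0.241; edgeR's quasi-likelihood test). Cell cycle genes, abundant in macrophages (Mki67 at 344 CPM in Warm M1), fell for 14 of 31, with 1 higher (17 and 2 over the list alone). Cdk1 changed by -2.13 and Birc5 by -1.93. With expected macrophage counts taken off they stayed lower (-2.21 and -1.97, edgeR's adjusted p = 0.00919 and 0.00682). Of the 6 members that owed under 10% of their counts to macrophages 1 rose and 1 fell. So few members were left there that this fit cannot tell whether the list fell. Pro-inflammatory genes went 1 higher and 9 lower of 21 (Ccl2 -0.98, Socs3 0.63, Il1b -2.99), and 2 higher and 5 lower of 8 such members. EdgeR's quasi-likelihood test gave 4512 of 12910 genes that differed in progenitors, 2373 higher and 2139 lower, with adjusted p = 0.00202 for Ppargc1a, 0.00326 for Igfbp3, 0.00329 for Timp1, 0.00285 for Etv4 and 0.0117 for Pdgfra. Camera called 12 of 30 lists, among them matrix (adjusted p = 1.07e-05), respiratory chain (5.63e-05), cell cycle (0.000468; 0.939 on the members owing little to macrophages), lipogenesis (0.00136), interferon response (0.0198), adipogenic regulators and FGF feedback (0.0373 for both; FGF feedback 0.0585 with the replicate numbers as a block) and unfolded protein response (0.0122; 3 of 17 lower), and none with an estimated correlation (adjusted p = 0.731 for each). The groups did not overlap for 50.4% of genes (chance, 10%). With 6 libraries in this fit single ones weighed heavily: 489 genes were called without Warm AP 2, 503 without Cold AP 3, 1531 without Warm AP 1 and 2408 without Cold AP 1. Of the 39 called genes named for progenitors 32 had not been picked for an absence of overlap, and 30 of these had none (Cd74 and H2-Aa overlapped). Of all, 22, among them Timp1, Tnc, Ppargc1a, Igfbp3, Mlxipl, Scd2, Birc5, Etv4 and Ifit2, kept the call in each refit. The other 17 lost it without Warm AP 2 or Cold AP 3, among them Pdgfra, Fgfr1, Cdk1, Ebf1, Rxra, Gbp5, Slc6a2 and both respiratory chain genes; 7 of them also did without Warm AP 1 and 5 without Cold AP 1.

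In M1 macrophages of thermoneutral mice given the antibody bFKB1, genes for lipid and lysosome handling were higher than in Warm. Redox and fatty acid oxidation genes rose with them, and parts of the alternative activation, pro-inflammatory, unfolded protein response and cell cycle lists fell. Lipid-associated macrophage genes rose for 16 of 18, with a median of 0.87: Cd36 (0.98, from 2840 to 5540 CPM), the proton pump subunit Atp6v0d2 (1.00), Lipa (0.76) and Plin2 (0.65). Lysosomal genes rose for 26 of 28 (27 over the list alone), Ctsd by 0.98 and the peptidase Tpp1 by 0.62. Antioxidant and iron genes rose for 12 of 16, with Slc40a1 at 2.39 (from 2.12 to 11.2 CPM), Blvrb at 1.10 and Prdx1 at 1.05, and fatty acid oxidation genes for 12 of 19 (Pdk4 1.70, Cpt1a 0.38). LXR and efflux genes went 6 higher and 1 lower of 13 (Apoe 0.80, Abcg1 0.47). Alternative activation genes fell for 7 of 16 (9 over the list alone; Alox15 -2.50, Ccl17 -1.83) and pro-inflammatory genes for 7 of 24 (Ccl4 -1.14, Ccl2 -1.13). Cell cycle genes fell for 17 of 33 (Mki67 -0.70, Top2a -0.56), unfolded protein response genes went 1 higher and 12 lower of 17 (Creld2 -0.97, Pdia4 -0.72), and monocyte genes fell for 3 of 14 (Ms4a4c -1.41). Carboxypeptidase E (Cpe, 2.68, from 25.8 to 164 CPM), the reductase Akr1b8 (2.23) and Serpinb9b (2.81) also rose, and Mgl2 fell from 537 to 141 CPM (-1.92).

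Among identity genes of macrophages in M1 under bFKB1, Cd68 rose by 0.56, Emr1 by 0.53 and the resident marker Folr2 by 1.40, Mrc1 fell by 0.46, and Itgax (0.26, adjusted p = 0.464) and Fgfr1 (-0.20, adjusted p = 0.318) did not change by edgeR's quasi-likelihood test. Progenitor markers did not change by that edgeR test either (Pdgfra 0.67, adjusted p = 0.43; Ly6a 0.31, adjusted p = 0.705), with progenitor RNA at 4.89%, 1.51% and 2.3%, and Klb stood at 0.0868 CPM. In all, edgeR's quasi-likelihood test called 2755 of 12734 genes, 1552 higher and 1203 lower, with adjusted p = 0.000509 for Cd36, Ctsd and Prdx1, 0.000668 for Mgl2 and 0.000533 for Ccl4. Camera called 14 of 32 lists, with lipid-associated macrophage at adjusted p = 7.63e-24 and lysosome at 1.09e-23; none held with an estimated correlation, where adjusted p was 0.0597 for lipid-associated macrophage and alternative activation and 0.092 for lysosome, antioxidant and pro-inflammatory genes. Warm and bFKB1 libraries come from 2 count tables, and no vehicle group was among the samples analysed here. Treatment therefore cannot be told apart from a difference between the tables. The groups did not overlap for 39.5% of genes (chance, 10%), and 1449 genes were called without Warm M1 1, 1653 without Warm M1 3, 1462 without bFKB1 M1 1, 1599 without bFKB1 M1 2 and 3809 without Warm M1 2. The 30 called genes named for bFKB1 in M1 all kept their call in these refits, and 23 of the 23 not picked for it had no overlap.

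In M2 macrophages the same kinds of genes were higher under bFKB1 than in Warm. Genes of alternative activation, secretory stress and the cell cycle were lower. As in M1, treatment cannot be told apart from the division into count tables. Lipid-associated macrophage genes rose for 13 of 18 (17 over the list alone), with a median of 0.83: osteopontin (Spp1, 2.02, from 22.9 to 93.4 CPM), Gpnmb (1.87, from 296 to 1090 CPM), the tetraspanin Cd9 (1.25) and Cd36 (0.81). Antioxidant and iron genes rose for 12 of 16 (13 over the list alone, with 1 lower): Gclm (1.46) and Gsr (1.19), which make and recycle glutathione, and Prdx1 (0.95). Lysosomal genes rose for 12 of 28 (19 over the list alone; Ctsd 1.00, Lipa 0.85) and fatty acid oxidation genes for 8 of 19 (11 over the list alone; Pdk4 1.03, Cpt1a 0.42). Alternative activation genes fell for 5 of 16 (Rnase2a -3.26, from 183 to 19.3 CPM; Retnla -1.24; Il4ra -0.57), unfolded protein response genes for 10 of 17 (13 over the list alone; Manf -0.75) and cell cycle genes for 10 of 33 (16 over the list alone; Kif11 -0.69). Monocyte genes fell for 4 of 14 (Ccr2 -1.29, Fn1 -1.33) and pro-inflammatory genes for 4 of 24 (Ccl4 -0.66). MHC class II genes fell for 0 of 14 at adjusted p under 0.05, and for 9, with 1 higher, when adjusted over the list alone. Mature adipocyte transcripts went 1 higher and 4 lower of 12 (leptin, Lep, -2.18, from 2.47 to 0.548 CPM).

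Mrc1 (-0.18, adjusted p = 0.121), Itgax (0.35, adjusted p = 0.41), Emr1 (0.22, adjusted p = 0.0813), Fgfr1 (-0.28, adjusted p = 0.228), Pdgfra (-0.45, adjusted p = 0.687) and Ly6a (-0.32, adjusted p = 0.762) did not change in M2 by edgeR's test, Cd68 rose by 0.28, and Klb stood at 0.292 CPM. EdgeR's quasi-likelihood test called 1052 of 12734 genes, 669 higher and 383 lower, with adjusted p = 0.000239 for Spp1, 0.000432 for Gpnmb and Gclm, 0.000109 for Rnase2a and 0.000395 for Ctsd. Camera called 19 of 32 lists. Lipid-associated macrophage (adjusted p = 4.05e-42 preset, 0.0217 with an estimated correlation), alternative activation (1.05e-08 and 0.0274) and antioxidant and iron (5.78e-19 and 0.0388) held, and the other lists named above did not (from adjusted p = 0.0922 for fatty acid oxidation to 0.315 for MHC class II). The groups did not overlap for 35.8% of genes (chance, 10%). Each library moved the count, to 394, 418 or 518 without 1 of the Warm M2 libraries and to 429, 553 or 533 without 1 of the bFKB1 M2 libraries. Of the 21 genes called and named 16 kept the call throughout, and 15 of the 15 not picked for it had no overlap; Retnla lost it whichever library was left out, Ccr2 for each but bFKB1 M2 3, Cd68 for each but Warm M2 3, Fn1 without Warm M2 1, Warm M2 2, bFKB1 M2 1 or bFKB1 M2 2, and Pdk4 without Warm M2 2.

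**Figure D2:**
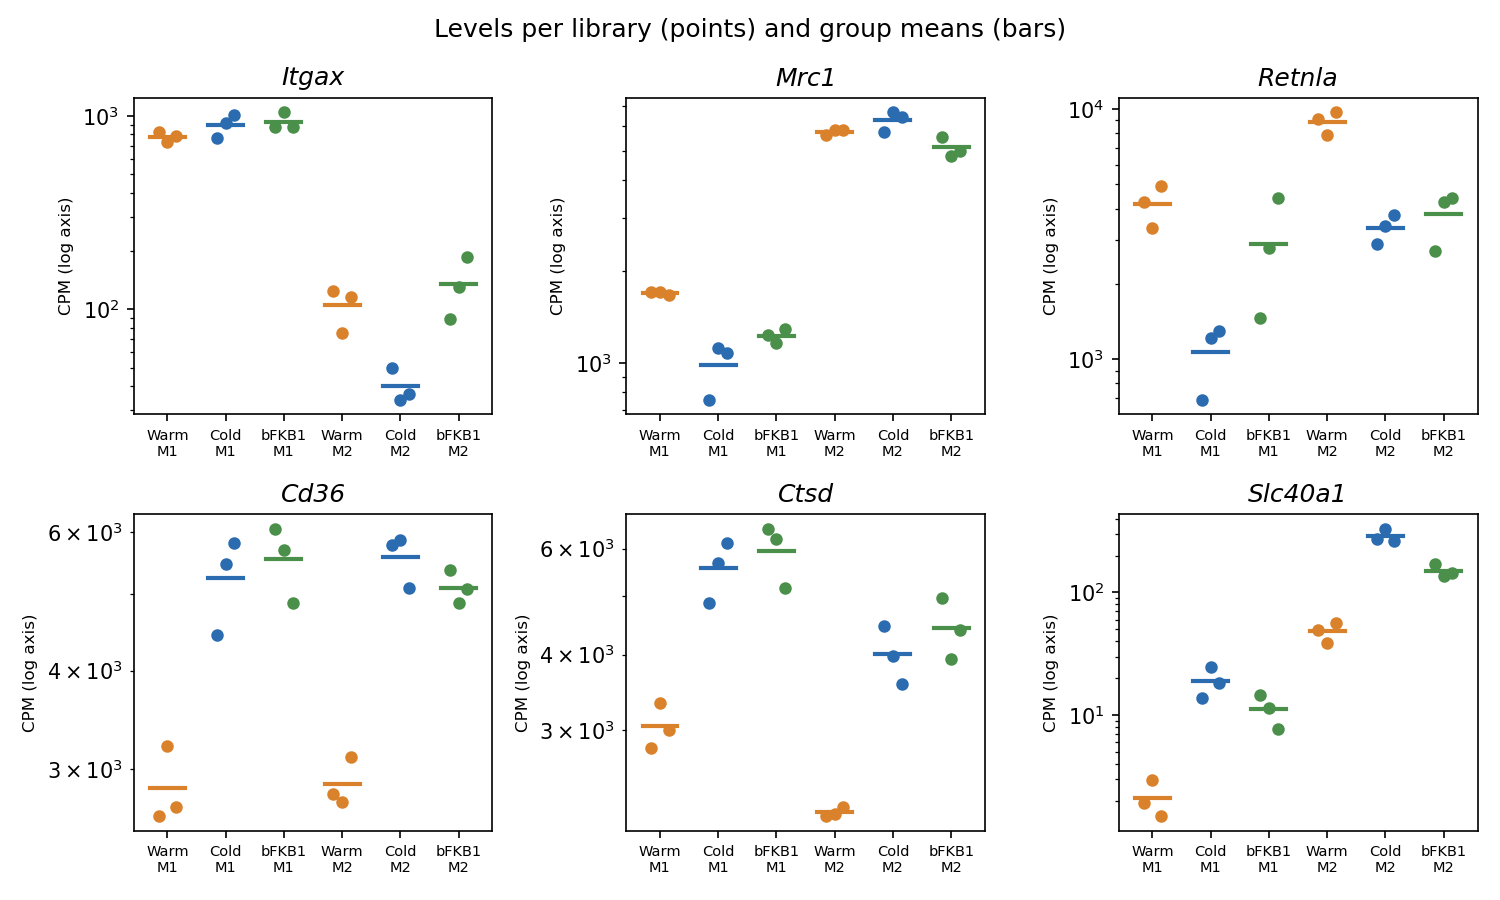
Levels (CPM, log axis) of 6 genes in each macrophage library, by population and condition, with bars at the group means. Group means of Ctsd and Cd36 are higher and those of Retnla lower in Cold and bFKB1 than in Warm, and Slc40a1 rises in M2 from 48.1 CPM in Warm to 289 in Cold and 151 under bFKB1.

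The response to bFKB1 was not shown to differ between M1 and M2. Testing that difference, edgeR's quasi-likelihood test called 0 of 12734 genes, with 976 at an unadjusted p under 0.05; DESeq2 called 77 and limma-voom 0, and edgeR called 46 without Warm M1 2 and 1 without bFKB1 M2 2. The difference was 0.08 for Itgax (adjusted p = 0.973, edgeR's quasi-likelihood test) and 0.27 for Mrc1 (adjusted p = 0.558). Fold changes of bFKB1 in the 2 populations had a correlation of 0.546 over 12734 genes, with 535 genes rising and 276 falling in both and 1 going opposite ways, where independence gives 81.5 and 36.2. Independence is not the level without an effect here. A difference between the 2 count tables could move both populations alike, and Warm M1 and Warm M2 libraries of equal number had correlated residuals (0.21 to 0.32). Cold and Warm libraries lie in 1 table, so the values for cold are no like measure. The matching numbers for cold were a correlation of 0.34, 380 genes rising and 597 falling in both (128.5 and 159.1 under independence) and 24 opposite, with progenitor RNA of 8.77% to 28.4% in the Cold M1 libraries. Camera called 9 of 32 lists for the bFKB1 difference, 0 of them with an estimated correlation.

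**Figure D3:**
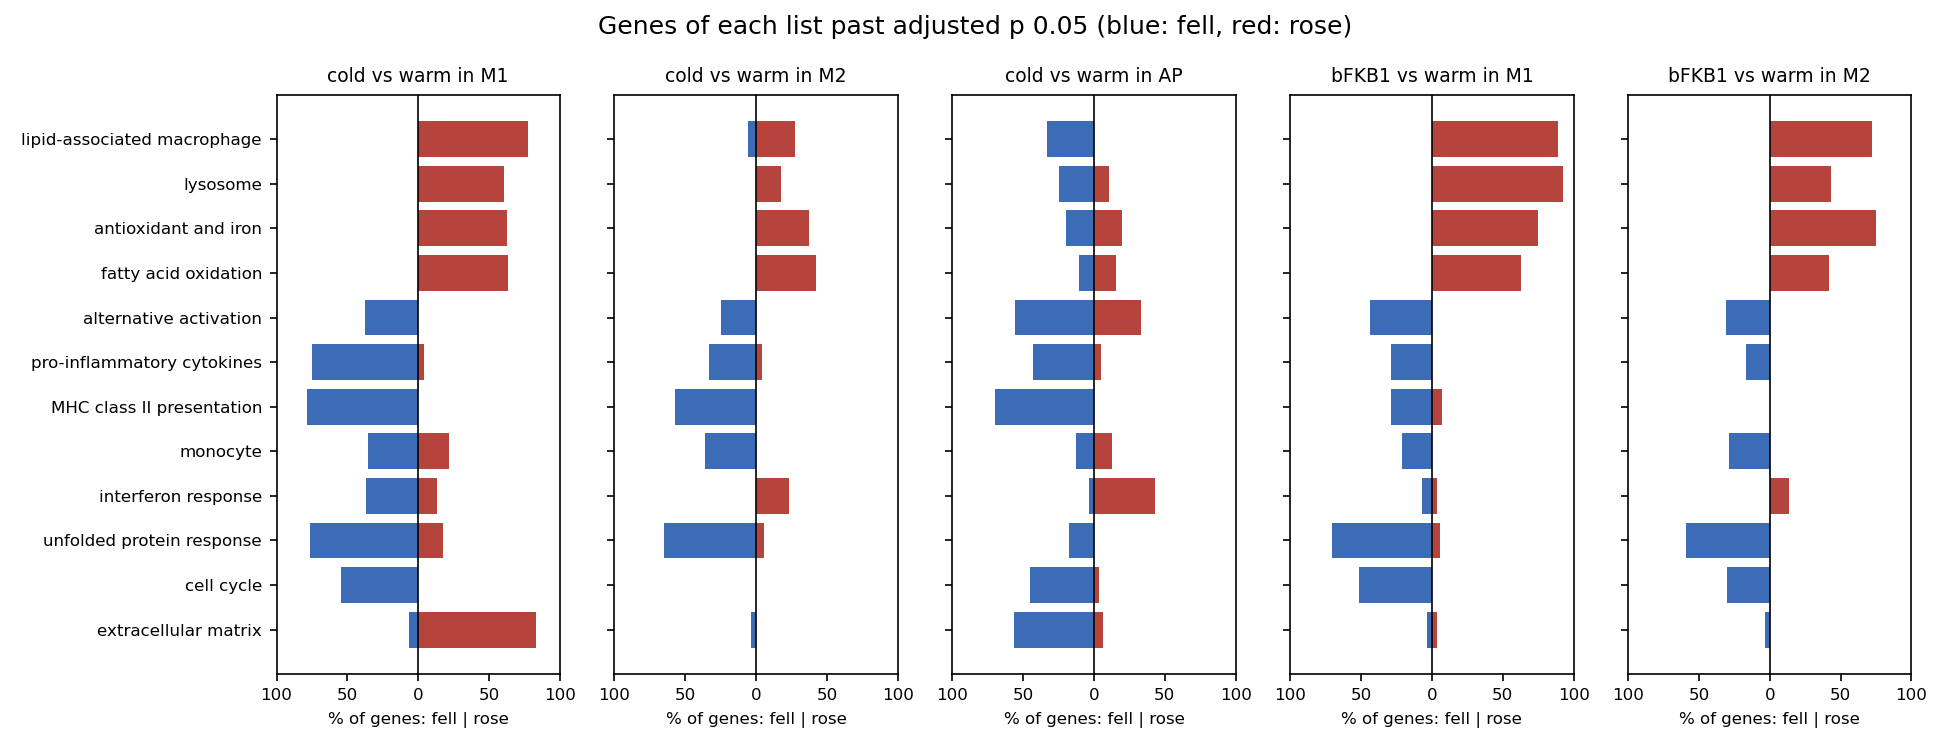
Share of the tested genes of 12 lists (percent) that rose (bars to the right) or fell (bars to the left) at adjusted p under 0.05, in each of the 5 treatment comparisons. Of the lipid-associated macrophage genes 16 of 18 rise under bFKB1 in M1 and 0 of 18 rise under cold in progenitors.

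Set directly against cold, M2 macrophages under bFKB1 held more RNA of lipid-laden cells and less of adipocytes. Cold and bFKB1 libraries lie in different count tables, and harvest was on day 14 of cold and 8 days after the antibody. Treatment cannot be told apart from these differences here. Lipid-associated macrophage genes were higher under bFKB1 than under cold for 11 of 18 (13 over the list alone), Itgax by 1.82 (135 against 40.1 CPM), Mmp12 by 1.54 and Gpnmb by 1.43. MHC class II genes were higher for 5 of 14 (8 over the list alone; H2-Ab1 1.01, H2-Eb1 0.94) and sterol synthesis for 7 of 24. Mature adipocyte transcripts were lower for 7 of 12 (Car3 -2.00, Adipoq -1.47, Cidec -1.27), as were Cyp2e1 (-4.51), Slc40a1 (-0.88), Pdk4 (-0.90) and the interferon genes Oasl1 (-0.57) and Rsad2 (-0.38). Rsad2 was not called with expected progenitor counts taken off (-0.40, edgeR's adjusted p = 0.0553) but was on genes with little progenitor RNA (-0.40, edgeR's adjusted p = 0.0214). In this pair of groups edgeR's quasi-likelihood test called 576 of 13086 genes, 436 higher and 140 lower under bFKB1, with adjusted p = 0.00322 for Itgax and Car3 and 0.00119 for Cyp2e1. The adipocyte list held with an estimated correlation (adjusted p = 7.93e-13 preset, 0.0131 estimated), the lipid-associated, MHC class II and sterol lists did not (adjusted p = 0.15, 0.502 and 0.327). Libraries of the groups did not overlap for 28.8% of genes (chance, 10%), and 29 genes were called without Cold M2 2, 31 without Cold M2 3, 373 without bFKB1 M2 1, 141 without bFKB1 M2 2 and 27 without bFKB1 M2 3. Among the 13 called genes named, 8 of the 10 not picked for it had no overlap (H2-Ab1 and H2-Eb1 overlapped), and 4 kept the call in each refit: Itgax, Gpnmb, Car3 and Cyp2e1. Of the rest, 9 lost it without Cold M2 2, 8 without Cold M2 3, 8 without bFKB1 M2 3, 4 without bFKB1 M2 2 and 1 (Rsad2) without Cold M2 1 or bFKB1 M2 1.

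The same contrast in M1 was dominated by the progenitor RNA of the Cold libraries, with 27 of 30 matrix genes and 17 of 19 progenitor genes lower under bFKB1 (Dcn -2.56; Pdgfra -2.70, not called with progenitor counts taken off) and 12 of 16 macrophage core genes higher (Csf1r 0.47, Lyz2 0.60). Dendritic cell genes were lower under bFKB1 for 8 of 12 with 1 higher: the chemokine receptor Ccr7 (-1.83, 16.2 against 58.7 CPM), Clec9a (-1.98) and Itgae (-2.57). Retnla (1.47) and F13a1 (1.33) were higher, and Plin1 (-2.02), Timd4 (-1.95) and Scd1 (-2.38) lower. EdgeR's quasi-likelihood test called 3442 of 13086 genes, 1448 higher and 1994 lower, with adjusted p = 0.00469 for Ccr7 and 0.00736 for Retnla. On the 2152 genes that owed under 10% of their counts to progenitors it called 272, 131 higher and 141 lower. Here too treatment cannot be told apart from the division into count tables. The dendritic cell and macrophage core lists lost their camera call with an estimated correlation (adjusted p = 0.000138 and 8.42e-09 preset, 0.155 and 0.295 estimated). The groups did not overlap for 35.5% of genes (chance, 10%), and 1309 genes were called without Cold M1 1, 1532 without bFKB1 M1 2 and 2164 without bFKB1 M1 3. Each of the 12 genes named for it kept the call in every such refit, but a fit of the 2 groups alone called 1 gene in all and none of these.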

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

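In this part the tests of the endothelial list, of the interferon genes after subtraction of progenitor counts and of the dendritic cell list were chosen after the results were seen, as was the set of genes moving opposite ways. The cold effect differed between M2 and M1 for 300 genes by edgeR's quasi-likelihood test, and the genes of this kind named in the report were picked out by it. The effect was higher in M2 for F13a1 (2.12), Padi4 (1.82), Bank1 (1.63), Ccl2 (1.34), Oasl1 (1.04), Isg15 (1.01), Usp18 (0.90), Mrc1 (0.87) and Rsad2 (0.74). It was lower for Xcr1 (-5.38), Adam12 (-4.18), Mmp3 (-3.90), Clec9a (-3.44), Flt3 (-2.94), F10 (-1.66), Itgax (-1.64) and Fn1 (-1.47). Of 100 splits of the 12 libraries 6 called as many genes, the real one among them, so chance is not excluded for the count of 300. The highest other count, 5399, points to a structure of the samples: that split turned the labels of 1 population round and so added the 2 cold effects. All 5 other splits with as many genes, that one included, left M1 or M2 grouped by condition, and the 75 that regrouped both populations called 0 at most by the same edgeR test.

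Some genes named for progenitors moved one way in all libraries there and the opposite way in all libraries of a macrophage population, a difference that was not tested. Col15a1, Col6a2, Lum, Mmp3 and Thbs4 fell in progenitors and had cold changes of 2.82, 2.10, 2.71, 3.42 and 1.79 in M1 (for Thbs4 with adjusted p = 0.0576 by edgeR's quasi-likelihood test), beside progenitor RNA of 8.77% to 28.4% in the Cold M1 libraries. Fgfr1, Rxra, Socs3 and Tgfbi rose in progenitors and had changes of -0.44, -0.15, -0.43 and -0.97 in M1, of which that of Rxra was not called. In M2, Ndufs8 (0.07), Scd2 (-1.15) and Socs3 (-0.43) stood opposite to progenitors, and of these Scd2 alone was called there.

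Progenitor transcripts rose in the Cold M1 libraries, with a median of 2.31 over the progenitor list. Of 176 progenitor genes that had not served to estimate the share, 87.5% lay within 2-fold of the level the estimate gave. The ratio of Cold M1 to Cold progenitors lay at 13% and 22.5% at its quartiles, 1.73-fold apart, around a median of 17.4% and beside a mean estimated share of 16.6%; transcripts switched on by the macrophages themselves would have had to keep the proportions found in progenitors. Endothelial genes did not rise along (median -0.67), which argues against vessel cells carried with the progenitors. RNA of progenitors in these libraries is the candidate explanation that remains; the values do not separate progenitors sorted with M1 cells, attached to them or taken up by them, and no biological explanation was tested.

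Interferon-stimulated genes moved apart under cold, with a median change of -0.13 in M1, 0.25 in M2 and 0.42 in progenitors, and a median difference between M2 and M1 of 0.43, above 0 for 28 of 30 genes. With the counts expected from progenitors taken off, the median difference was 0.51 (quartiles 0.26 and 0.86; 9 genes called), which argues against dilution of M1 RNA as the whole cause; this test replaced an earlier one, a refit of the 6 members with little progenitor RNA (0.69 before and 0.46 after), once its value was known. The lowest median without any 1 library was 0.35 (Warm M1 2). The dendritic cell list went the other way (-0.82), which decides nothing, although it had been set down as speaking against another share of dendritic cells: in the warm M1 held more dendritic cell transcripts than M2 (median 0.98) and fewer interferon transcripts (-0.36), so such cells could lower interferon RNA in M1. Another share of dendritic cells and a difference in how the 2 populations respond to cold therefore both stay open; harvest or sorting differences between the groups were not tested, and the gene count behind the contrast is open to chance as given above.

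Cold and bFKB1 moved macrophage genes the same way: 1050 genes rose and 849 fell under both in M1 (338.8 and 264.9 under independence; 4 opposite), and 217 and 155 in M2 (29.9 and 22.3; 3 opposite). Since both are set against the same Warm libraries, correlations of 0.567 in M1 (0.741 on genes with little progenitor RNA) and 0.693 in M2 (0.684) stand beside 0.503 and 0.505, the means of 20 simulations without any effect, and covariances of 0.199 and 0.129 beside 0.0327 and 0.0374. Between populations, where no library is shared, the covariance was 0.037 for cold in M1 with bFKB1 in M2 (correlation 0.112, highest simulated covariance 0.00301, and 0.248 and 0.594 on 2057 genes with little progenitor RNA). It was 0.0886 for cold in M2 with bFKB1 in M1 (0.448, 0.00236, and 0.0637 and 0.438 on 10251 such genes). The simulations drew each gene independently, while real libraries deviate together over many genes. The simulated range is therefore too narrow to decide whether the shared libraries or the 2 count tables are the whole cause. Warm M1 and Warm M2 libraries of the same number passed on a covariance of 0.00363, and anything common to all Warm mice stays open, since 3 libraries per group are too few to divide between the comparisons. Changes seen under bFKB1 alone cannot be told apart from a difference between the tables, and a response that both treatments share may be put forward only as a hypothesis.

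The other contrasts compare 3 libraries with 3, and their 10 splits are too few for a share under 0.05; in each, 1 of the 10 splits, the real one, called as many genes. The real and the highest other count were 5705 and 0 for cold in M1, 1312 and 1 in M2 and 4512 and 98 in progenitors, 2755 and 459 for bFKB1 in M1 and 1052 and 0 in M2, 5873 and 0 for M1 against M2, and 3442 and 0 in M1 and 576 and 0 in M2 for bFKB1 against Cold. For progenitors, M1 against M2 and bFKB1 against Cold in M1 equal numbers had correlated residuals, though no label states pairs. There, other splits that part all 3 pairs of equal numbers called 0 genes at most, also by edgeR. In both Cold M1 and bFKB1 M1 number 1 held the most progenitor RNA (28.4% and 4.89%), which was not separated from pairing. For the difference of the bFKB1 effects edgeR called 0 genes (976 at an unadjusted p under 0.05; DESeq2 77, limma-voom 0), so that all 100 splits call as many by construction and say nothing; the highest count, 3960, came from the split that turned 1 population round and added the 2 bFKB1 effects. As many lists as in the real split were called by camera in 3 of 10 splits for cold in M1 (16 real, 18 highest other), 2 in M2 (15 and 15) and 2 in progenitors (12 and 13). The figures were 6 for bFKB1 in M1 (14 and 17), 1 in M2 (19 and 18) and 9 for M1 against M2 (13 and 16). Other splits called 12 to 18 lists for cold in M1 and 12 to 16 for M1 against M2, where they called 0 genes. Each such split keeps 2 libraries of a group on 1 side, so part of a real effect may remain in it. Calls with the preset correlation therefore hardly set the real grouping apart, and their small p-values are weak support.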

How the results depend on the processing

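The refits on genes with little RNA of another population, the subtraction of its expected counts, the fits without 2 libraries and the lists in the blocked fit were chosen after the data were seen; the other alternatives were fixed earlier. Of 140 such earlier values for counts of called genes, 91 lay within 1.5 times the reported one, and of 24 later ones 17. Genes named in the texts gave 3631 values for 272 results: 3375 kept direction and side of the threshold, 235 lost the call, 21 gained one and 0 changed sign with a call in either fit. For the later alternatives the figures were 596, 18, 10 and 0 of 624.

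Fits of the compared groups alone, with 6 libraries, gave 3796 genes for cold in M1 (1959 higher and 1837 lower), 2538 in M2 (1231 and 1307), 1604 and 1854 for bFKB1 in M1 and M2, and 1 for bFKB1 against Cold in M1; fewer residual degrees of freedom belong to their construction, but what raised the counts in M2 was not tested. For the difference of the cold effects DESeq2 called 1470 genes and limma-voom 175, and for that of the bFKB1 effects DESeq2 called 77. Without a filter on low counts 368 genes were called for bFKB1 against Cold in M2, where more genes were tested. The cause of the differences between tools was not tested.

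On genes with little RNA of the other population, fewer genes were tested, and 981 were called for cold in M1 and 272 for bFKB1 against Cold in M1. After the expected counts were taken off, 694 genes were called for the difference of the cold effects and 1492 for bFKB1 against Cold in M1 (806 higher and 686 lower). For cold in M1 that fit called 4565, and 103 genes called in both fits changed sign; for bFKB1 against Cold in M1, 103 did as well. Without both Cold M1 1 and Warm M1 2, the difference of the cold effects had 2487 genes and cold in M1 6080. Without both Warm M2 2 and Cold M2 2, cold in M2 had 231 (65 higher and 166 lower), and without both Warm AP 3 and Cold AP 2 progenitors had 7485 (3908 higher and 3577 lower). The cause was not tested.

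With an estimated correlation camera called 0 lists for cold in M1, 6 in M2 and 0 in progenitors, 0 for bFKB1 in M1 and 3 in M2, and 1 for M1 against M2. Fry called 1 list in progenitors. On genes with little RNA of the other population camera called 6 of 17 lists for cold in M1 and 7 of 25 in progenitors. With the replicate block, which moved no gene count by over 1.5 times, the FGF feedback list lost its call in progenitors (adjusted p from 0.0373 to 0.0585) and the resident list gained one there (0.0615 to 0.0146). Gains also came for adipogenic regulators under cold in M1 (0.0562 to 0.0493), granulocyte and mast cell under bFKB1 in M2 (0.0531 to 0.011) and, for M1 against M2, endothelial (0.0527 to 0.00572), mature adipocyte (0.0656 to 0.0156), stromal inflammation (0.0718 to 0.0481) and T and NK cell (0.0718 to 0.0136). For the differences of effects the groups compared are those of the fit, so a fit of the groups alone was not run.

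With each library left out in turn, the counts ranged from 4064 to 6038 for cold in M1, 531 to 937 in M2 and 489 to 6437 in progenitors. They ranged from 1449 to 3809 for bFKB1 in M1, 394 to 553 in M2, 5038 to 5776 for M1 against M2, 23 to 1982 for the difference of the cold effects and 0 to 46 for that of the bFKB1 effects. For bFKB1 against Cold the ranges were 1309 to 3962 in M1 and 27 to 787 in M2. In the other groups equal numbers did not go together in all pairs: residual correlations of equal numbers were -0.64 to 0.71 for Warm and Cold M1, -0.08 to 0.10 for Warm and Cold M2, -0.71 to 0.33 and -0.15 to -0.14 for Warm and bFKB1 in M1 and M2, -0.42 to -0.14 for Cold M1 and M2, and -0.14 to -0.10 for Cold and bFKB1 M2. In simulated data with the depth of these libraries (14.4 to 34.6 M counts), changes of 1.5-fold were found for 14.9% of genes in progenitors to 59.7% under bFKB1 in M1, so that small changes not called here are not shown to be absent.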

Other observations

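The values in this part add to the contrasts described above, and the genes were chosen after their levels were seen; no test was made for them unless one is named. Transcripts for making noradrenaline were all but absent from the 3 sorted populations: Th and Dbh had 0 counts in each of the 24 libraries, and group means of Ddc lay between 0 and 1.6 CPM. The transporter Slc6a2 had group means of at most 0.93 CPM in macrophages. Monoamine oxidase A (Maoa), higher in M2 than in M1 in the warm, stood at 86.3 CPM in Warm M2 and 115 in Cold M2, and rose under cold in M1 from 10.3 to 24.9 CPM (1.26, adjusted p = 0.000533 by edgeR's quasi-likelihood test, no overlap of the 3 and 3 libraries).

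Genes of the FGF21 axis and of brown fat were low in these cells. The highest group means were 0.73 CPM for Fgf21 (Warm progenitors) and 0.489 and 0.252 CPM for Klb and Ucp1 (Cold M2), while group means of Fgfr1 in macrophages lay between 360 and 735 CPM. Up to 50.2% of the Fgfr1 counts of a Warm or Cold macrophage library were put down to progenitors. Thermogenic adipocyte genes had 1 higher and 1 lower of 6 under cold in M1 and 1 of 8 higher in progenitors. Smooth muscle and pericyte genes went 1 higher and 2 lower of 11 under cold in M1, B cell genes 2 higher and 1 lower of 5 and mesothelial genes 2 higher and 1 lower of 6. Endothelial genes had median changes of 0.68 under cold and 0.78 under bFKB1 in M2, where camera with a preset correlation called the list (adjusted p = 0.00628 and 0.00164; 0.732 and 0.426 with an estimated correlation) and edgeR called no member on its own. Epididymal epithelium had too few genes past the filter to be tested.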
